A study of Mus musculus with 28 samples.

How the data were processed

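The study measured RNA in skeletal muscle of mice after injection of interleukin 1b (IL-1b, an inflammatory cytokine) or vehicle into the cerebral ventricles, the fluid spaces of the brain. Muscle was taken 2, 4 or 8 h after injection, per the labels' protocols. The 28 arrays fall into 6 groups by treatment and time, with 5 arrays in each group except IL-1b at 8 h, which has 3. Groups and replicate numbers were read from the sample titles, and 1 title whose code runs a number into the time was read by the same pattern as the others. The labels do not state that each array is a separate mouse, so p-values measure the spread between these samples.

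Total muscle RNA was extracted with a column kit for fibrous tissue and biotin-labelled for whole-transcript Affymetrix arrays, per the labels' protocols. The authors processed the arrays with RMA (robust multi-array average, which corrects background, normalizes between arrays and summarises probes), with the mouse build mm9, per the submitters' processing notes. The software and the version of RMA are not given in the sources used here. The deposited log2 values cover 17831 probe sets with 0 missing values and run from -2.317 to 3.533. The log base is not stated for the table and was taken as log2, the scale RMA gives. Each of the 17831 probe sets has a median of 0 over the 28 arrays within 1e-06, so the authors' table holds values centred per probe set. A centred value says how an array differs from the others for that probe set and carries no expression level, and signal over background cannot be read from it. Array medians ran from -0.02757 to 0.08438. The number of arrays limits the precision.

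Probe sets were named through the platform annotation. Of the probe sets, 15620 had 1 gene symbol, 1370 had several and 841 had none listed here. The first set covers 15224 genes, 375 of them with more than 1 probe set. No gene was named from a probe set with several symbols. No genomic coordinates are given, because the annotation used for names belongs to another build than mm9.

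Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with the 6 groups was fitted to all 28 arrays and the variances were moderated across probe sets (22 residual and 3.95 prior degrees of freedom, median residual SD 0.146). Contrasts were IL-1b minus vehicle at each time, the differences of those effects between times, and vehicle at 4 h and at 8 h minus vehicle at 2 h. Every adjusted p printed for a gene is limma's moderated test with Benjamini-Hochberg adjustment over all probe sets, and the threshold was 0.01, the false discovery rate the design text names. The selection that the design text describes was also made, with limma's moderated F-test over the 6 groups and a change of at least 1.75-fold between IL-1b and vehicle at any time. Errors beside log2 differences are standard errors (SE) of the model.

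Gene lists (30 lists, 669 entries, 651 distinct genes) were fixed before the data were examined, as were the tests, the first set of other settings and the rule for naming genes. The files measured 562 of the entries, covering 546 distinct genes, with a probe set of 1 symbol. Each list was tested at each time with limma's camera at a preset correlation between genes of 0.01, and the 90 tests were adjusted together with Benjamini-Hochberg. Alternatives were camera with an estimated correlation and limma's fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. Beside each count of members past the threshold over all probe sets stands the count adjusted over the list alone. The plan was to represent a gene with several probe sets by the one of highest mean. Centred values carry no level, and a high mean then marks a skewed probe set, so the lowest probe set number was used instead and the rule of highest mean was run as an alternative.

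Genes named in the text were chosen by rule. At each time the rule took a fixed panel of 16 genes, the 8 largest rises and 8 largest falls past the threshold, and up to 4 called members of each list that was called or had 3 or more called members. For the other contrasts it took the 5 largest changes in each direction. Predicted and uncharacterised genes were passed over. Of the panel, Trim63 and Cebpd have no probe set with a single symbol and were not analysed here. Where a count of 5 or fewer is given, its genes may be named outside the rule, as stated there.

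The model was tested on simulated data with the real arrays' group sizes and 17831 probe sets. Of 50 probe sets changed 1.75-fold, 96% were recovered at 2 h, 98% at 4 h and 86% at 8 h, and there were 1, 2 and 2 false calls at these times. In 1 simulation, camera called the list that had been shifted by 0.5 on the log2 scale and 0 other lists. Simulated probe sets were independent of each other, while estimated correlations within the real lists reached 0.553. The simulations therefore do not measure false calls among correlated genes.

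Other settings chosen before were an unmoderated statistic with the pooled error of the one-way analysis of variance in the design text, a fit of only the groups compared, a threshold of 0.05, a trended and robust spread estimate, array weights, centring of each array on its median, a further quantile normalization, probe sets with 1 symbol only, a fold filter, a replicate block where vehicle groups share title numbers, and leaving out each array in turn. The quantile normalization was applied to the centred values, where it evens out the spread of the arrays and does not repeat a normalization of signals. A filter on low values was not run, since centred values have no low level. Array weights did not converge with the default method, and limma's gene-by-gene method was used in its place. Chosen after seeing the data were that method, a fit without the 3 arrays of widest spread, a robust estimate without trend, a replicate block on the changes of effect where both treatments share title numbers, and camera with the probe set of highest mean.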

Results

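The arrays measured gene expression in skeletal muscle of mice given interleukin 1b (IL-1b) or vehicle into the brain's ventricles, to follow how muscle responds to a cytokine acting in the central nervous system. Vehicle groups held 5 arrays at 2, 4 and 8 h, and IL-1b groups held 5 arrays at 2 h, 5 at 4 h and 3 at 8 h. Values are log2 and centred per probe set, so differences between groups are given and levels are not. The first principal component held 34.7% of the variance and set apart 3 arrays with the widest spread over probe sets, vehicle 2 h replicate 7 (SD 0.2978), vehicle 8 h replicate 1 (SD 0.3168) and IL-1b 8 h replicate 22 (SD 0.3302), against at most 0.2229 in the other arrays.

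At 2 h, the adhesion molecule genes Selp, Icam1 and Vcam1 and the NF-kB inhibitor genes Nfkbia and Tnfaip3 were higher in muscle from IL-1b mice. Selp (P-selectin, which captures leukocytes on activated endothelium) was higher by 2.64 ± 0.37 on the log2 scale (SE, n = 5 per group, limma adjusted p = 0.00119), which is 6.23-fold. Icam1, an integrin ligand, rose by 2.04 ± 0.27 (4.12-fold, adjusted p = 0.000783) and Vcam1 by 1.63 ± 0.24 (adjusted p = 0.00151). Sele (E-selectin), named after its value was seen, differed by 0.51 and did not pass (adjusted p = 0.0687). Nfkbia and Tnfaip3 rose by 1.01 ± 0.15 and 0.68 ± 0.11 (adjusted p = 0.00214 for both). Vcam1 and Nfkbia did not pass without IL-1b 2 h replicate 8 or replicate 10, and Tnfaip3 did not pass without replicate 8, 10 or 12. Retnlg, a transcript of neutrophils, rose by 1.28 ± 0.19 (adjusted p = 0.00151), and Csf1, the growth factor of macrophages, by 0.90 ± 0.16 (adjusted p = 0.00979).

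The NF-kB and cytokine response list had 5 of 27 measured members higher at 2 h, 0 lower and 22 that did not pass, and 9 were higher when adjusted over the list alone. Camera called this list higher (adjusted p = 1.04e-14, and adjusted p = 0.0227 with an estimated correlation). Of 16 neutrophil markers, Retnlg was the 1 that rose, 5 were higher when adjusted over the list alone, and the list was called higher (adjusted p = 2.28e-07, and adjusted p = 0.173 with an estimated correlation). Lcn2 differed by 1.45 and Mmp8 by 0.80 without passing (adjusted p = 0.0119 for both). Glucocorticoid-induced genes had 1 of 26 measured members higher, Nfkbia, and 4 when adjusted over the list alone, and the list was called higher (median 0.251, adjusted p = 1.14e-09, and adjusted p = 0.0793 with an estimated correlation). Within it, the metallothionein Mt2 differed by 0.99 ± 0.23 (adjusted p = 0.0615) and Fkbp5, a co-chaperone of the glucocorticoid receptor, by 0.56 ± 0.18 (adjusted p = 0.245).

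Falls at 2 h were small. Thbd (thrombomodulin, an anticoagulant receptor of endothelium) fell by 0.61 on the log2 scale (SE 0.10, adjusted p = 0.00632), Sertad4 fell by 0.45 (SE 0.08, adjusted p = 0.00477) and the metalloprotease Adam19 fell by 0.44 (SE 0.08, adjusted p = 0.00824). Without single arrays of the 10 at this time, Thbd and Adam19 lost the call for 8 arrays each, Sertad4 for 5 and Csf1 for 9, and Retnlg only without IL-1b 2 h replicate 10. A trended and robust spread estimate ended the calls of Csf1, Tnfaip3, Thbd and Adam19, and leaving out the 3 arrays of widest spread those of Csf1, Thbd, Adam19 and Sertad4. Camera called 4 lists lower at 2 h although 0 of their members passed over all probe sets. Extracellular matrix and fibroblast markers (25 members) had a median of -0.379 (adjusted p = 2.23e-14, and adjusted p = 0.116 with an estimated correlation). The others were ER stress and ATF4 genes (22 members, adjusted p = 2.8e-05, and adjusted p = 0.035 with an estimated correlation), monocyte and macrophage markers (17 members, adjusted p = 3.83e-05, and adjusted p = 0.308 with an estimated correlation) and endothelial markers (16 members, adjusted p = 4.34e-05, and adjusted p = 0.14 with an estimated correlation). Adjusted over the list alone, 0, 0, 3 and 1 members of these lists were lower and 0 were higher. Autophagy and lysosome genes were called higher with 0 of 24 members past the threshold either way (adjusted p = 0.00856, and adjusted p = 0.387 with an estimated correlation). Later vehicle arrays also differed from the vehicle 2 h arrays used here in some of these lists. In vehicle at 4 h the matrix list was called lower (median -0.359, adjusted p = 2.03e-07, and adjusted p = 0.467 with an estimated correlation) and the autophagy list higher (adjusted p = 0.00108, and adjusted p = 0.364 with an estimated correlation), and in vehicle at 8 h the ER stress list was called lower (adjusted p = 0.00194, and adjusted p = 0.15 with an estimated correlation).

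In all, 13 of 17831 probe sets passed at 2 h, 10 higher and 3 lower, and 8 of them, all higher, changed at least 1.75-fold. IL-1b 2 h replicate 2 stood among the vehicle values for Selp and just above them for Icam1. Its centred Selp was -0.29 against 2.87 to 3.01 in the other 4 IL-1b arrays. Its Icam1 was 0.19, against 2.29 to 2.64 in those arrays and at most 0.15 in vehicle at 2 h. Its mean over the NF-kB list was 0.0656, against 0.484 to 0.593 in the other IL-1b arrays and at most 0.0557 in vehicle. The other 4 IL-1b arrays differed from vehicle by 3.28 for Selp and 2.5 for Icam1. Without IL-1b 2 h replicate 2, 40 probe sets passed, against 7 without vehicle replicate 1 or 7 and 6, 3, 2 and 8 without IL-1b replicates 4, 8, 10 and 12. When limma was fitted to the 2 h groups only, 0 passed, with 2434 probe sets at an unadjusted p under 0.05.

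**Figure D1:**
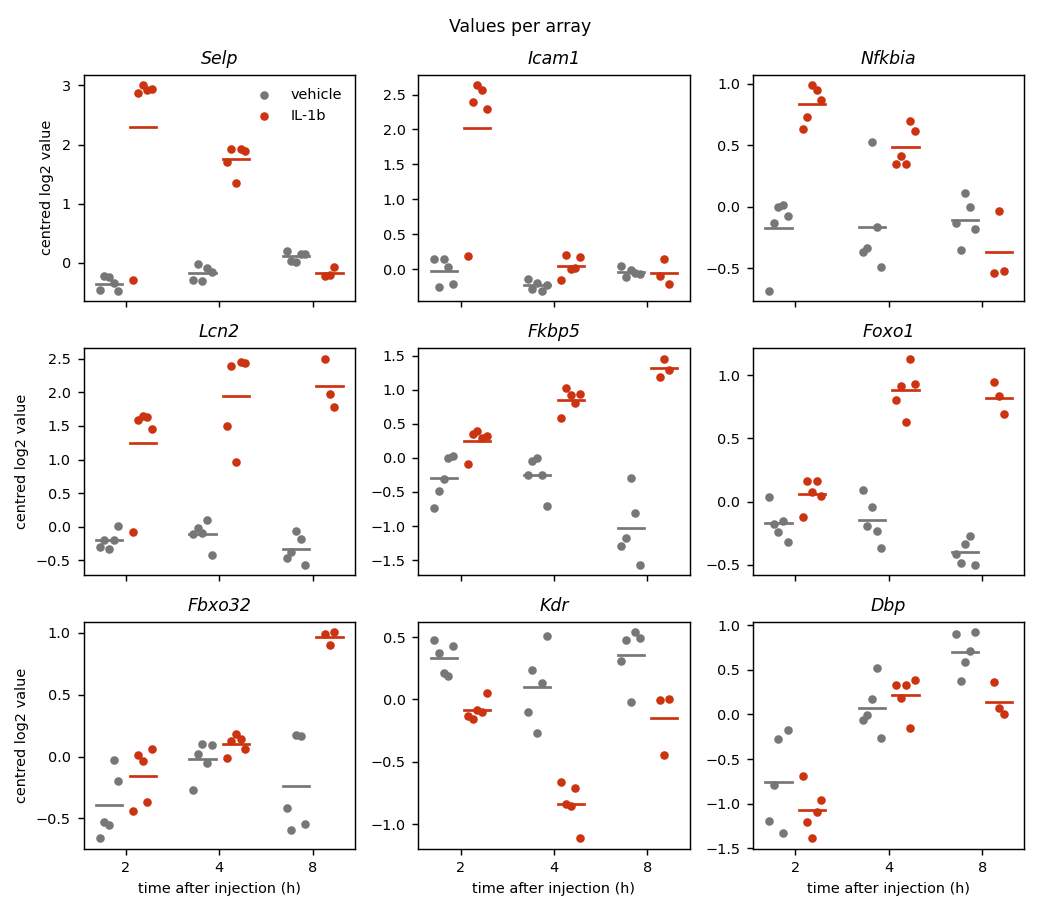
Centred log2 value of 9 genes on each of the 28 arrays (y axis) by time after injection in hours (x axis), with vehicle in grey, IL-1b in red and a bar at each group mean. At 2 h 1 IL-1b array lies with the vehicle arrays for Selp (-0.29) and just above them for Icam1 (0.19). The Fbxo32 values of the 3 IL-1b arrays at 8 h lie above those of the 5 vehicle arrays.

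At 4 h, the list of glucocorticoid-induced genes was called higher after IL-1b, and Foxo1 and Foxo3 rose. Ddit4, an inhibitor of mTORC1 signalling, rose by 3.14 ± 0.40 on the log2 scale (8.81-fold, n = 5 per group, adjusted p = 2.95e-05), Mt2 by 1.69 ± 0.23 (adjusted p = 4.03e-05) and Fkbp5 by 1.11 ± 0.18 (adjusted p = 0.00055). The transcription factors Foxo1 and Foxo3, which drive atrophy programmes, rose by 1.03 ± 0.09 (adjusted p = 6.72e-08) and 0.48 ± 0.09 (adjusted p = 0.00292). Foxo3 did not pass without vehicle 4 h replicate 3 or 17 or IL-1b 4 h replicate 18, nor with a trended and robust spread estimate. Lcn2 (lipocalin 2, an acute phase protein) rose by 2.05 ± 0.27 (adjusted p = 3.71e-05), and Slc7a8, a transporter of neutral amino acids, by 1.37 ± 0.11 (adjusted p = 1.96e-08). The ubiquitin ligase gene Fbxo32 did not pass at 4 h (0.12 ± 0.14, adjusted p = 0.925). One vehicle 4 h array, replicate 5, had a centred Ddit4 of 1.24 against -1.52 to -1.17 in the other vehicle arrays. The mean of the glucocorticoid-induced list on this array was 0.186, against -0.432 to -0.235 in the other vehicle arrays.

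Of 26 measured glucocorticoid-induced genes, 9 rose at 4 h, 0 fell and 17 did not pass, and 16 were higher when adjusted over the list alone. The list was called higher by camera (median 0.51, adjusted p = 3.37e-26, and adjusted p = 0.0044 with an estimated correlation). Among the 18 STAT3 and acute phase genes, Lcn2, the oncostatin M receptor gene Osmr (1.05 ± 0.16) and Il4ra (0.66 ± 0.07) rose, 7 were higher and 1 lower when adjusted over the list alone, and camera called the list (adjusted p = 1.48e-07, and adjusted p = 0.0256 with an estimated correlation). Of 24 immediate early genes, Zfp36 (1.09 ± 0.16) and Fosl2 (0.59 ± 0.08) were higher than in vehicle. In that list 6 were higher when adjusted over the list alone (adjusted p = 6.66e-08, and adjusted p = 0.116 with an estimated correlation). Camera also called this list lower in vehicle at 4 h than at 2 h (adjusted p = 0.00124, and adjusted p = 0.54 with an estimated correlation), Fosl2 being among the fallers. The list mean on IL-1b arrays was 0.0307 to 0.402 at 2 h and 0.0401 to 0.242 at 4 h. The difference at 4 h therefore stands against a fall in vehicle. Of 17 ubiquitin ligase and FoxO atrophy genes, Foxo1 and Foxo3 rose, 2 also when adjusted over the list alone (adjusted p = 0.00108, and adjusted p = 0.0981 with an estimated correlation). Of 23 amino acid and polyamine genes, Slc7a8 rose, and 5 were higher when adjusted over the list alone (adjusted p = 0.000133, and adjusted p = 0.0981 with an estimated correlation). The metal and oxidative stress list had 3 of 19 members higher (Mt2, Mt1 and Slc39a14) and 0 lower, with 4 higher and 2 lower when adjusted over the list alone, and was not called (median -0.0408). The NF-kB and cytokine response list was called with 1 of 27 members higher, Selp (1.93 ± 0.37), and 2 adjusted over the list alone (adjusted p = 0.00353, and adjusted p = 0.405 with an estimated correlation). The list was not called without vehicle 4 h replicate 7 (adjusted p = 0.0122), and Selp did not pass without vehicle 4 h replicate 1 or 17 or IL-1b 4 h replicate 13, 18 or 22 (adjusted p from 0.0102 to 0.0107). Neutrophil markers were called with 1 of 16 higher, Lcn2, and 1 adjusted over the list alone (adjusted p = 0.000187, and adjusted p = 0.384 with an estimated correlation).

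Kdr, Eng and Aplnr, receptors of endothelial cells, were among the falls at 4 h. Kdr, the main receptor of VEGF, fell by 0.94 on the log2 scale (SE 0.12, adjusted p = 3.59e-05) and Eng (endoglin) fell by 0.46 (SE 0.08, adjusted p = 0.000622). Kdr did not pass at 2 h or 8 h, but its centred values at 2 h were also lower after IL-1b (-0.156 to 0.0505) than in vehicle (0.185 to 0.477). At 8 h they overlapped, from -0.444 to 0.00214 after IL-1b and from -0.0203 to 0.540 in vehicle. Aplnr (the apelin receptor) fell by 0.88, Myct1 fell by 0.94, the glycerol channel gene Aqp7 fell by 1.05 and the phosphatase gene Dusp10 fell by 0.95, with adjusted p of 0.000782, 0.000497, 4.03e-05 and 0.000895. Dusp10 did not pass after a further quantile normalization (-1.06, adjusted p = 0.0131), nor Aplnr, Dusp10 and Zfp36 when only the 4 h groups were fitted. Of 16 endothelial markers 2 fell (Kdr and Eng), 0 rose and 14 did not pass, with 3 lower and 1 higher when adjusted over the list alone. The list was called lower (adjusted p = 0.00817, and adjusted p = 0.387 with an estimated correlation). Pecam1 (-0.06), Vwf (-0.01) and Cdh5 (-0.20) were among those that did not pass. ER stress and ATF4 genes (22 members, adjusted p = 8.26e-05, and adjusted p = 0.0508 with an estimated correlation) and heat shock genes (16 members, adjusted p = 0.00754, and adjusted p = 0.384 with an estimated correlation) were called lower with 0 members past the threshold over all probe sets or adjusted over the list alone.

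At 4 h 151 probe sets passed, 103 higher and 48 lower, and 42 changed at least 1.75-fold, 36 of them higher. Fitting only the 4 h groups gave 98, and leaving out vehicle 4 h replicate 17 gave 93.

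At 8 h the response included Fbxo32 (atrogin-1, a muscle ubiquitin ligase of atrophy), which rose by 1.21 ± 0.16 on the log2 scale (2.31-fold, n = 3 IL-1b and 5 vehicle arrays, adjusted p = 2.16e-05). Fkbp5 rose by 2.34 ± 0.21 (adjusted p = 3.74e-08), Klf15, a glucocorticoid-induced transcription factor, by 1.30 ± 0.16 (adjusted p = 5.76e-06) and Foxo1 by 1.23 ± 0.10 (adjusted p = 2.16e-08). Depp1, a FoxO target, showed the largest rise, 2.57 ± 0.26 (5.95-fold, adjusted p = 3.2e-07). The acute phase genes Lcn2 and Serpina3n rose by 2.41 ± 0.31 (adjusted p = 1.58e-05) and 1.93 ± 0.26 (adjusted p = 2.78e-05). Ppp1r3c, a glycogen-targeting phosphatase subunit, was higher than in vehicle by 1.85 ± 0.16 (adjusted p = 3.74e-08). Its vehicle values were lower at 8 h than at 2 h, so this difference stands against a fall in vehicle. Centred Fkbp5 in vehicle also ran lower at 8 h (-1.57 to -0.29) than at 2 h (-0.73 to 0.03). Of the panel, Pdk4 (0.51 ± 0.13, adjusted p = 0.0206), Mstn (0.47 ± 0.17, adjusted p = 0.156), Igf1 (-0.37 ± 0.21, adjusted p = 0.524), Nfkbia (-0.26 ± 0.18, adjusted p = 0.674), Il6 (0.07 ± 0.06, adjusted p = 0.739), Il1b (0.03 ± 0.09, adjusted p = 0.97) and Socs3 (0.06 ± 0.16, adjusted p = 0.963) did not pass.

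**Figure D2:**
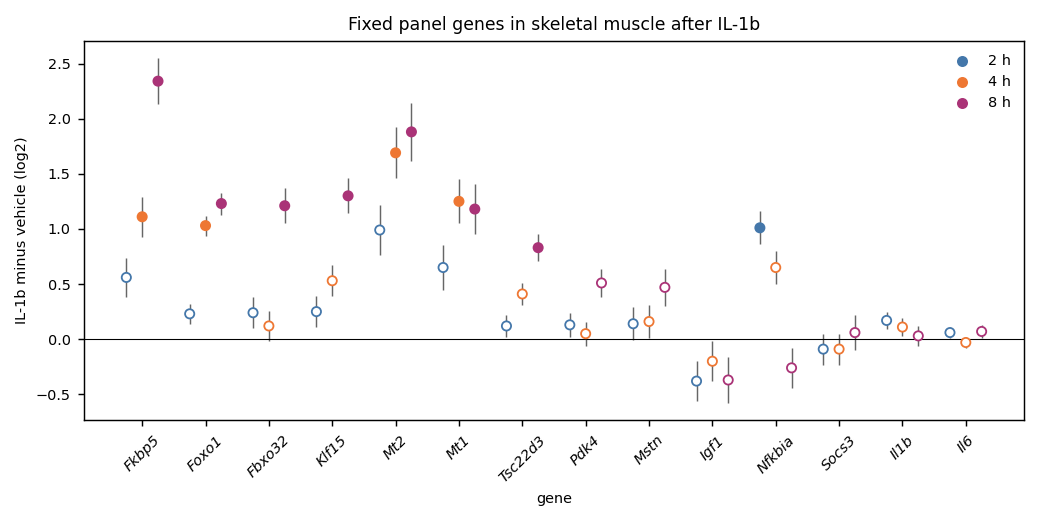
IL-1b minus vehicle on the log2 scale (y axis) for 14 panel genes (x axis) at 2 h, 4 h and 8 h, with standard errors. Filled points passed at an adjusted p under 0.01, as Fkbp5 did at 4 h (1.11) and 8 h (2.34), and open points did not.

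Glucocorticoid-induced genes had 13 of 26 members higher at 8 h, 1 lower (Dusp1, -0.78 ± 0.16) and 12 that did not pass, with 19 higher and 2 lower when adjusted over the list alone. Camera called the list (median 0.647, adjusted p = 3.5e-24, and adjusted p = 0.0044 with an estimated correlation). The list mean ran from 0.194 to 0.501 on IL-1b arrays at 8 h, against 0.372 to 0.573 at 4 h. On vehicle arrays it ran from -0.698 to -0.229 at 8 h, against -0.432 to 0.186 at 4 h. The larger list difference at 8 h thus stands against lower vehicle values and not higher IL-1b values. Among 23 amino acid and polyamine genes 6 rose and 0 fell, and 7 were higher when adjusted over the list alone. They included the transporters Slc43a1 (1.42 ± 0.15), Slc7a8 (1.37 ± 0.12) and Slc7a2 (1.15 ± 0.11) and glutamine synthetase Glul (1.39 ± 0.20), and the list was called (adjusted p = 5.54e-12, and adjusted p = 0.0044 with an estimated correlation). Of 17 ubiquitin ligase and FoxO atrophy genes 4 rose, 0 fell and 13 did not pass. They were Foxo1, Fbxo32, Gadd45a (0.87 ± 0.14) and Foxo3 (0.79 ± 0.10), with 6 higher and 1 lower adjusted over the list alone. This list was called too (adjusted p = 2.3e-06, and adjusted p = 0.0217 with an estimated correlation). Of 18 STAT3 and acute phase genes, Lcn2, Serpina3n and Lrg1 (0.93 ± 0.13) rose, the count of 3 being the same adjusted over the list alone (adjusted p = 3.08e-05, and adjusted p = 0.0777 with an estimated correlation). The mean of this list was 0.51, 0.169 and 0.0491 on IL-1b 8 h replicates 14, 22 and 26, against -0.243 to -0.0772 in vehicle at 8 h. In vehicle at 2 h it ran from -0.0867 to 0.265, and camera called it lower in vehicle at 8 h (adjusted p = 0.000942, and adjusted p = 0.169 with an estimated correlation). Of 19 metal and oxidative stress genes, Mt2 (1.88 ± 0.26), the zinc transporter Slc39a14 (1.23 ± 0.10), Mt1 (1.18 ± 0.23) and Xdh (0.85 ± 0.14) rose, again 4 when adjusted over the list alone (adjusted p = 0.00247, and adjusted p = 0.0741 with an estimated correlation). Mt1 no longer passed without IL-1b 8 h replicate 22 (0.79). After a further quantile normalization Gadd45a did not pass (0.65, adjusted p = 0.0129), and Slc7a2 passed at 0.69.

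Immediate early genes went both ways at 8 h, with Myc (0.74 ± 0.14), Klf6 (0.69 ± 0.12) and Jun (0.60 ± 0.11) higher and Dusp1 lower among 24. Myc did not pass without IL-1b 8 h replicate 14, nor Klf6 without replicate 26. After a further quantile normalization none of the 4 passed, with Myc at 0.45 (adjusted p = 0.156), Klf6 at 0.56 (adjusted p = 0.0186), Jun at 0.49 (adjusted p = 0.0252) and Dusp1 at -0.69 (adjusted p = 0.0467). The list was called, with 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.00992, and adjusted p = 0.491 with an estimated correlation). Camera also called it lower in vehicle at 8 h than at 2 h (adjusted p = 0.00109, and adjusted p = 0.54 with an estimated correlation). The list mean on the IL-1b arrays at 8 h ran from -0.161 to 0.14. Of the NF-kB and cytokine response list 0 of 27 members were higher at 8 h by limma's test and 2 were lower, 2 also adjusted over the list alone, and the list was not called. Both, Tnfaip3 (-0.65) and Tnfaip2 (-1.02), are named here after their values were seen. Among 24 autophagy genes Gabarapl1 rose (0.79 ± 0.13), 2 when adjusted over the list alone (adjusted p = 0.00105, and adjusted p = 0.308 with an estimated correlation). Gabarapl1 did not pass after that normalization (0.49, adjusted p = 0.048). Proteasome subunits (28 members, median 0.0611, adjusted p = 0.00739, and adjusted p = 0.476 with an estimated correlation) and ribosome biogenesis genes (24 members, median 0.114, adjusted p = 0.000429, and adjusted p = 0.188 with an estimated correlation) were called higher with 0 members past the threshold over all probe sets or over the list alone. Of 25 IGF, insulin and myostatin signalling genes 3 rose, Sesn1 (1.56 ± 0.18), Pik3r1 (1.14 ± 0.18) and Igfbp3 (0.49 ± 0.10). Adjusted over the list alone 3 were higher and 2 lower, and the list was not called. Dusp1 and Igfbp3 each lost the call without any of 4 arrays, and Igfbp3 also with the quantile normalization (0.45, adjusted p = 0.0202).

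Ky, Itgb6, Tnc and Col15a1 were among the falls at 8 h. Ky, whose loss causes a muscle disease with spinal curvature in mice, fell by 1.40 on the log2 scale (SE 0.13, adjusted p = 6.93e-08) and Itgb6, an integrin subunit, fell by 1.23 (SE 0.10, adjusted p = 1.11e-08). The transferrin receptor Tfrc fell by 1.24 (SE 0.23, adjusted p = 0.000983), Dusp10 fell by 1.34 (SE 0.19, adjusted p = 3.62e-05) and the clock repressor Bhlhe41 fell by 1.07 (SE 0.14, adjusted p = 2.21e-05). Of 25 extracellular matrix and fibroblast markers, Tnc (-0.84 ± 0.15) and Col15a1 (-0.78 ± 0.16) fell, 6 when adjusted over the list alone, and the list was called lower (median -0.356, adjusted p = 3.24e-06, and adjusted p = 0.387 with an estimated correlation). Its mean was -0.543 on IL-1b 8 h replicate 14, -0.157 on replicate 26 and 0.143 on replicate 22, against 0.0641 to 0.269 in vehicle, and the list was not called without replicate 14 (adjusted p = 0.0345). Tnc and Tfrc did not pass without IL-1b 8 h replicate 14, nor Col15a1 without replicate 14 or 26. With a further quantile normalization Tnc (-0.68, adjusted p = 0.0251), Col15a1 (-0.60, adjusted p = 0.0596) and Tfrc (-0.94, adjusted p = 0.0197) did not pass either.

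Among cell type markers at 8 h, adipocyte markers were called higher, with Plin4 (0.85 ± 0.14) as the 1 of 12 that rose and 1 adjusted over the list alone (adjusted p = 0.000973, and adjusted p = 0.387 with an estimated correlation). The mean of this list was 1.21 on IL-1b 8 h replicate 14, and -0.0553 and -0.152 on replicates 22 and 26 lay within the vehicle arrays (-0.341 to 0.204). It was not called without IL-1b 8 h replicate 14 (adjusted p = 0.693) or vehicle 8 h replicate 1 (adjusted p = 0.0337). Plin4 did not pass after a further quantile normalization (0.56, adjusted p = 0.0422). Monocyte and macrophage markers were called higher with 0 of 17 past the threshold and 2 adjusted over the list alone (adjusted p = 0.00642, and adjusted p = 0.476 with an estimated correlation). Lists without a call at any time were interferon-stimulated genes, the circadian clock, IGF, insulin and myostatin signalling, fatty acid use and fasting, glycolysis and glycogen, oxidative phosphorylation, slow and fast fibre genes, and muscle structure, myogenic and denervation genes. Lymphocyte, Schwann cell, satellite cell and red blood cell markers were not called either. The lowest of their adjusted p was 0.0102, for interferon-stimulated genes at 4 h (0 of 17 past the threshold, 0 also adjusted over the list alone). Of 15 clock genes 1 was higher and 1 lower at 8 h, with 2 higher and 1 lower when adjusted over the list alone. Of 20 fatty acid genes 2 were higher and 0 lower then, with 5 higher and 2 lower when adjusted over the list alone. The list median, mean and test differed in sign in 16 of the 90 tests, 0 of them called.

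At 8 h 373 probe sets passed, 182 higher and 191 lower, and 78 changed at least 1.75-fold, 56 of them higher. With a further quantile normalization 130 passed, 81 higher and 49 lower, and with only the 8 h groups in the fit 37 passed. Of the 40 named genes past the threshold, 12 lost the call with that normalization and 24 with only the 8 h groups, Fbxo32, Serpina3n, Glul, Foxo3, Mt1, Pik3r1 and Lrg1 among the latter.

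**Figure D3:**
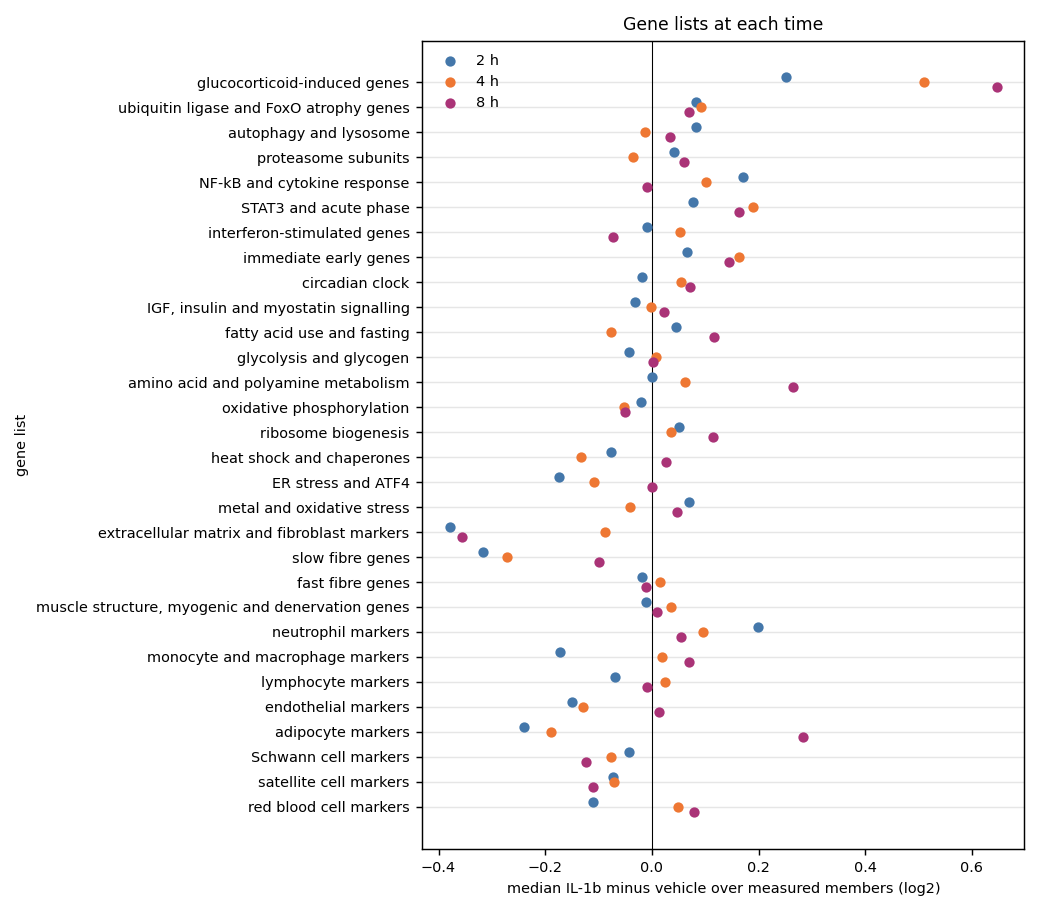
Median IL-1b minus vehicle over the measured members of each fixed gene list on the log2 scale (x axis) for the 30 lists (y axis), with a point for 2 h, 4 h and 8 h. Glucocorticoid-induced genes stand highest at all times, at 0.251, 0.51 and 0.647. Each value is a difference from vehicle of the same time, and vehicle itself was lower for this list at 8 h than at 2 h (median -0.202).

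Camera made 30 calls in the 90 list tests, 8 at 2 h, 10 at 4 h and 12 at 8 h, and 3 held with an estimated correlation: the glucocorticoid-induced genes at 4 h and 8 h and the amino acid genes at 8 h. When arrays were regrouped at random within each time, camera with the preset correlation still made a median of 12 calls and at most 29. Without each array in turn, 7 of the 8 calls at 2 h, 6 of the 10 at 4 h and 3 of the 12 at 8 h stayed. At 8 h the call was lost without IL-1b replicate 14 for 8 lists, STAT3 and acute phase, metal and oxidative stress, autophagy, proteasome, ribosome biogenesis, matrix, adipocyte and monocyte. It was lost without vehicle 8 h replicate 1 for 7, the immediate early genes and 6 of those 8. Immediate early genes at 8 h lost the call without any of 14 arrays, endothelial markers at 4 h without any of 9, autophagy genes at 2 h without any of 6 and heat shock genes at 4 h without any of 5. The FoxO atrophy list at 4 h lost it without vehicle 4 h replicate 1 (adjusted p = 0.0925). Leaving out genes of more than 1 list ended the calls of the NF-kB list at 4 h and the metal list at 8 h.

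The effects at 4 h and 8 h had genes in common beyond the number that independent lists would share. Of the probe sets that rose at 4 h, 49 also rose at 8 h against 1.05 for independent lists, and of those that fell 12 also fell against 0.514. The times share no arrays, but they share the spread estimate of each probe set. Their calls are therefore not independent, and the numbers for independent lists can be too low. In the opposite direction, 1 of the 48 that fell at 4 h rose at 8 h. Of the 10 probe sets that rose at 2 h, 3 also rose at 4 h and 0 at 8 h, where 1 of them fell. Of the 3 that fell at 2 h, 1 also fell at 4 h and 0 at 8 h. Across probe sets, which are not independent replicates, effects at 4 h and 8 h correlated with r = 0.415 and rho = 0.331, those at 2 h and 4 h with r = 0.0499 and rho = -0.14, and those at 2 h and 8 h with r = 0.0663 and rho = -0.0495.

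The selection described in the design text, an F-test over the 6 groups with a change of at least 1.75-fold, took 122 of 1095 probe sets past the F-test. The fold was met by 17 at 2 h, 45 at 4 h and 86 at 8 h, and by 4 at all times. At 2 h 17 were higher and 0 lower, at 4 h 39 were higher and 6 lower, and at 8 h 61 were higher and 25 lower.

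The difference of the IL-1b effect between times was tested directly. From 2 h to 4 h it grew for Slc7a8 by 1.23 ± 0.15 on the log2 scale (adjusted p = 0.000236) and for Foxo1 by 0.79 ± 0.13 (adjusted p = 0.00682), among 9 probe sets with a larger effect at 4 h and 0 with a smaller one. A trended and robust spread estimate gave 0 of these 9 by limma (1749 probe sets at an unadjusted p under 0.05), with Slc7a8 and Foxo1 at an adjusted p of 0.0988, and the unmoderated statistic gave 2. The difference for Foxo1 did not pass without any 1 of 14 of the 20 arrays. From 4 h to 8 h, Klf10 (1.79 ± 0.17, adjusted p = 1.77e-06), Tmem140 (1.83 ± 0.26, adjusted p = 0.000583) and Id3 (1.29 ± 0.18, adjusted p = 0.000375) moved up, and Ky (-1.45 ± 0.17, adjusted p = 3.42e-05) and Itgb6 (-1.17 ± 0.13, adjusted p = 8.79e-06) moved down, among 14 up and 17 down. Between 2 h and 8 h the effects on Selp, Icam1 and Vcam1 fell by 2.92, 2.06 and 1.99 (SE 0.56, 0.41 and 0.37, adjusted p = 0.00549, 0.00713 and 0.00383), and those on Serpina3n and Fkbp5 grew by 2.13 ± 0.35 and 1.79 ± 0.27 (adjusted p = 0.00132 and 0.00053), among 50 up and 44 down. Of the 18 arrays at these times, the difference was lost without any 1 of 16 for Icam1, of 12 for Selp and of 2 for Vcam1. With a further quantile normalization 7 of the 31 differences between 4 h and 8 h passed (1 up, 6 down) and 12 between 2 h and 8 h (8 up, 4 down). From 4 h to 8 h Tmem140 (1.49, adjusted p = 0.0599) and Id3 (1.11, adjusted p = 0.0309) did not pass then. From 2 h to 8 h Vcam1 (-1.50, adjusted p = 0.024), Selp (-2.04, adjusted p = 0.022), Icam1 (-1.43, adjusted p = 0.0203) and Fkbp5 (1.25, adjusted p = 0.0271) did not pass either. Random regroupings of the arrays gave 94 or more differences between 2 h and 8 h in 5 of 100 groupings, the real one included, so this last count is not separated from chance. Leaving out 1 array gave 2 to 27 differences between 2 h and 4 h and 44 to 102 between 2 h and 8 h, the extremes being without IL-1b 2 h replicate 2 (27) and without IL-1b 8 h replicate 22 (44).

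Vehicle mice also changed over the hours after injection, which gives the background of these comparisons. At 8 h against 2 h, the clock output gene Dbp rose by 1.46 ± 0.19 (n = 5 per group, adjusted p = 3.39e-05) and Per3 by 1.07 ± 0.12 (adjusted p = 3.36e-06), while the core clock gene Arntl fell by 1.42 (SE 0.16, adjusted p = 4.31e-06) and Nfil3 fell by 1.53 (SE 0.15, adjusted p = 7.45e-07). Slc25a25 fell by 1.78, Ppp1r3c by 1.33 and Cdkn1a by 1.28 (adjusted p = 3.59e-06, 3.36e-06 and 3.36e-06). With a trended and robust spread estimate Slc25a25 (adjusted p = 0.328) and Ppp1r3c (adjusted p = 0.0302) did not pass, nor did Dbp when only the groups compared were fitted (adjusted p = 0.0139). The thioesterase gene Acot2 rose by 1.13 ± 0.16 (adjusted p = 9.02e-05). In all, 60 probe sets rose and 92 fell. At 4 h against 2 h, the fatty acid genes Ucp3 (1.02 ± 0.17) and Cpt1a (0.53 ± 0.09) rose (adjusted p = 0.00369 for both) and Nr4a2, an immediate early gene, fell by 1.08 (SE 0.19, adjusted p = 0.00669), with 3 probe sets higher and 15 lower. Fits of only the groups compared gave 19 probe sets at 8 h and, by limma, 0 at 4 h, with 1863 at an unadjusted p under 0.05. The count at 4 h ran from 5 to 22 without single arrays, and Nr4a2, Ucp3 and Cpt1a each lost the call without some of them. Cpt1a also lost it with a further quantile normalization (0.58, adjusted p = 0.0222).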

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

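The tests of explanations in this part, and the fit without the 3 arrays of widest spread, were chosen after the results they concern had been seen.

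In groups of 5 arrays, a value was marked when its gap to the nearest other array exceeded 0.71 of the group's range. Of 253 groups of named genes 16 were marked, where chance marks about 1 in 20 (12.7 expected), and 6 of the 16 marks fell on IL-1b 2 h replicate 2. Its centred log2 values were -0.29 for Selp, 0.19 for Icam1, -0.04 for Vcam1, -0.19 for Csf1, -0.09 for Fkbp5 and -0.41 for Mstn, each below the other 4 arrays of the group.

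Over the 40 probe sets called at 2 h without this array, its median position was 0.114 on a scale where vehicle is 0 and the other IL-1b arrays are 1, and the 5 vehicle arrays, each placed with genes chosen without it, lay between -0.028 and 0.123. The 32 higher genes gave 0.079 (vehicle arrays -0.089 to 0.113) and the 8 lower genes 0.556, where vehicle (-0.398 to 0.603) and the other IL-1b arrays (-0.004 to 0.94) overlap. The tables argue against an exchange with a vehicle 2 h array, since 0 of those arrays had a position above 0.5. A vehicle array under a wrong label stays open, as does an IL-1b mouse in which little cytokine reached its target, for which the design gives no test. The mean of the glucocorticoid-induced list on this array, 0.112, lay above the 5 vehicle arrays at that time (-0.381 to -0.0324) and just under the other IL-1b arrays (0.13 to 0.234), and Nfkbia stood at 0.765 on the position scale, values that speak for some response but come from 1 array and settle nothing.

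Kdr and Eng fell at 4 h. A share of endothelial RNA lower by the -0.70 of these genes' mean would lower the other markers by about as much. The other 14 markers had a mean of -0.08 (SD 0.24 over markers), and the median of all 16 was -0.13 (SD 0.32). Kdr and Eng were picked as the markers past the threshold, so the others were bound to move less. The values speak only against a loss of about that size, and a smaller loss of share was not tested. Both calls stayed after a further quantile normalization, with Kdr at -1.06. That normalization acted on values already centred per probe set, so it cannot decide whether the scaling of array signals contributed. The markers moved apart, from 0.29 for Esam, above vehicle when adjusted over the list alone, to -0.45 for Cldn5. A change within endothelial cells remains as a hypothesis, and a loss of some vessel types was not tested.

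The neutrophil transcripts Retnlg and Lcn2, the latter also in the STAT3 and acute phase list, behaved differently, which bears on a larger share of neutrophil RNA in the muscle. At 2 h, the mean of the 14 markers other than Retnlg and Lcn2 was higher by 0.17 (two-sided exact permutation p = 0.0317). S100a8 stood at 0.17 and S100a9 at 0.46 among abundant neutrophil transcripts. This test asked only whether the mean differed from 0, so more neutrophil RNA may contribute to the rise of Retnlg. A mean of 0.17 lies far under the 1.28 of Retnlg, so a larger share of that size is not shown. The test at 8 h was stricter, as it compared the size of the rise with that of Lcn2. At 8 h, the other 15 markers had a mean of 0.06 (SD 0.06 over markers) and reached at most 0.21, against 2.41 for Lcn2, and S100a8 and S100a9 stood at 0.08 and 0.01, which argues against neutrophils as the source of Lcn2 then. Mmp8 and Cxcr2, which were higher at 2 h when adjusted over the list alone, stood at 0.08 and 0.10 at 8 h. Muscle or other cells that make Lcn2 stay open and were not tested.

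The other marked arrays were as follows. Vehicle 4 h replicate 5 was above its group for Ddit4 (1.24), Zfp36 (0.67) and Usp54 (0.19). Vehicle 2 h replicate 7 was below its group for Mstn (-0.87) and Pkp4 (-0.50), vehicle 2 h replicate 1 for Nfkbia (-0.68) and vehicle 2 h replicate 11 for Csf1 (-0.20). Vehicle 8 h replicate 13 was high for Gadd45a (0.36), vehicle 8 h replicate 1 low for Cdkn1a (-1.80) and IL-1b 4 h replicate 18 high for Slc7a8 (1.51).

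The IL-1b effect differed between times, by limma's test of the difference, for 9 probe sets from 2 h to 4 h, 31 from 4 h to 8 h and 94 from 2 h to 8 h. Between 2 h and 4 h the named log2 differences were 1.23 for Slc7a8, 0.86 for Acer2, 0.79 for Foxo1, 0.79 for Usp54 and 0.66 for Lrig1. The call was lost without any 1 of 18 arrays for Lrig1 and of 14 each for Acer2 and Foxo1, for Acer2 also after a further quantile normalization (adjusted p = 0.0139), and for these 5 genes with a trended and robust spread estimate (adjusted p = 0.0988). From 4 h to 8 h they were 1.83 for Tmem140, 1.79 for Klf10, 1.29 for Id3, 0.96 for Adamts1, 0.95 for Dapk1, -1.03 for Bhlhe41, -1.14 for Dusp1, -1.17 for Itgb6, -1.23 for Tmem252 and -1.45 for Ky. Without any 1 of 13 arrays the call was lost for Bhlhe41 and for Dusp1, and without any 1 of 5 for Adamts1. After the quantile normalization Adamts1 (0.63, adjusted p = 0.696), Dapk1 (0.79, adjusted p = 0.0357), Bhlhe41 (-1.06, adjusted p = 0.0618), Dusp1 (-1.06, adjusted p = 0.0859), Tmem140 (1.49, adjusted p = 0.0599) and Id3 (1.11, adjusted p = 0.0309) did not pass. Between 2 h and 8 h they were 2.13 for Serpina3n, 1.79 for Fkbp5, 1.48 for Klf10, 1.48 for Tmem140, 1.45 for Ppp1r3c, -1.37 for Hdac9, -1.41 for Dusp10, -1.99 for Vcam1, -2.06 for Icam1 and -2.92 for Selp. Of these 10, all but Serpina3n and Klf10 lost the call after the quantile normalization, and the same 8 without the 3 arrays of widest spread. A second probe set of Acer2 did not pass for the difference between 2 h and 4 h (0.04, adjusted p = 0.901) or for the IL-1b effect at 4 h (0.15, adjusted p = 0.642).

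Regrouping the arrays showed how often other groupings of the same arrays gave as many calls. For the IL-1b effect only the real grouping reached its count at 4 h (151 calls, 1 of 100 groupings, highest other 2) and at 8 h (373, 1 of 56, highest other 22). The same held for vehicle at 4 h (18, 1 of 100, highest other 1) and at 8 h (152, 1 of 100, highest other 10). It held too for the F-test selection (122, 1 of 100, highest other 0) and the change of effect from 2 h to 4 h (9, 1 of 100, highest other 0). These numbers do not exclude chance, since 1 of 100 or 1 of 56 is the smallest share that could be reached. The gap to the highest other count does not measure strength, because a real effect adds to the spread within regrouped arrays and lowers their count. For the changes of effect, regrouping within times removed the treatment effect itself, so these groupings do not stand for an equal effect at both times. For the F-test selection arrays were also moved between times, so changes over time alone could exceed those regroupings. At 2 h, 2 of 100 groupings reached 13, and the other was the real grouping with vehicle 2 h replicate 7 and IL-1b 2 h replicate 2 exchanged. From 4 h to 8 h, 2 of 100 reached 31 (highest other 37). From 2 h to 8 h, 5 of 100 reached 94, so chance is not excluded for that count, and the highest other gave 1198. That grouping set vehicle 8 h replicate 1 and IL-1b 8 h replicate 22, both of wide spread, in 1 group. It moved other arrays as well, and the reason for its count was not tested. The gene list tests made 30 calls, the highest other grouping made 29, and 1 of 100 was as large.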

How the results depend on the processing

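The gene-by-gene method of the array weights, the fit without the 3 arrays of widest spread, the robust estimate without trend, the replicate block on changes of effect and camera with the probe set of highest mean were chosen after seeing the data. Of 119 named results past the threshold, 41 kept their side under every alternative run for them. Of 2309 checks of these results 412 lost the call and 0 turned direction. Leaving out single arrays, 77 of the 119 passed without each array, 2 of 11 at 2 h (Selp and Icam1), 22 of 25 at 4 h and 29 of 40 at 8 h. The cause was not tested for the differences below, except that fewer arrays or another threshold change a count by construction. A filter on low values was not run, and signal over background could not be read from centred values.

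For the IL-1b effect at 2 h, 4 h and 8 h the counts were 13, 151 and 373. An adjusted p under 0.05 gave 44, 265 and 718, at least 1.75-fold 8, 42 and 78, and array weights 80, 450 and 836. Only the groups compared gave 0 by limma (2434 at an unadjusted p under 0.05), 98 and 37. Quantile normalization again gave 26 at 2 h (18 higher, 8 lower) and 130 at 8 h (81 higher, 49 lower). At 2 h the unmoderated statistic gave 8, the trended and robust estimate 7, and leaving out the 3 widest arrays 8.

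For the change of effect from 2 h to 4 h (9), from 4 h to 8 h (31) and from 2 h to 8 h (94), an adjusted p under 0.05 gave 23, 79 and 221 and array weights 63, 164 and 192. The trended and robust estimate gave 0 by limma (1749 at an unadjusted p under 0.05), 16 and 47. For the first of these the unmoderated statistic gave 2 and the fold filter 2, and leaving out the 3 widest arrays gave 6. Quantile normalization gave 7 (1 up, 6 down) from 4 h to 8 h and 12 (8 up, 4 down) from 2 h to 8 h. From 2 h to 8 h the fold filter gave 49, only the groups compared 25 and leaving out the 3 widest arrays 33.

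For vehicle at 4 h (18) and 8 h (152) against 2 h, an adjusted p under 0.05 gave 84 and 331, the fold filter 2 and 17, and array weights 31 and 276. Only the groups compared gave 0 by limma (1863 at an unadjusted p under 0.05) and 19. At 4 h quantile normalization gave 28 and leaving out the 3 widest arrays 11. A replicate block over the shared title numbers (3 at 4 h, 2 at 8 h) gave 0 (819 at an unadjusted p under 0.05) and 44, 18 of them among the 152. Deviations of same-numbered arrays from their group means correlated at 0.374, -0.434 and -0.207 for 2 h and 4 h at 0.378 and 0.0567 for 2 h and 8 h, and at 0.678 and 0.0562 for 4 h and 8 h. Number 1 gave a value above 0.3 in its 3 pairs, but the 3 pairs of 2 h and 4 h did not all exceed 0.1 and the others are 2 pairs each, so the numbers were not taken to pair the arrays. IL-1b groups share number 4 at 2 h and 4 h (-0.0693) and number 22 at 4 h and 8 h (-0.075). With this 1 IL-1b pair, assumed to vary like the 3 or 2 vehicle pairs, a replicate block on the change of effect gave 0 from 2 h to 4 h (459 at an unadjusted p under 0.05, 2 residual degrees of freedom) and 1 from 4 h to 8 h (1 degree of freedom), which was not among the 31. No paired analysis was possible for the IL-1b effects because IL-1b and vehicle groups of a time share no numbers, nor for the change from 2 h to 8 h, where IL-1b groups share none.

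The F-test selection of 122 became 1095 without the fold filter. The 30 list calls became 3 with an estimated correlation and 12 with fry.

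Leaving out 1 array gave 2 to 40 calls at 2 h, 93 to 166 at 4 h and 254 to 386 at 8 h for the IL-1b effect. It gave 2 to 27, 21 to 37 and 44 to 102 for the change of effect in the order above, 5 to 22 and 79 to 169 for vehicle, 115 to 137 for the F-test selection and 21 to 31 for the list tests. Beyond 1.5 times lay, at 2 h, vehicle 2 h replicates 1 (7) and 7 (7) and IL-1b 2 h replicates 2 (40), 4 (6), 8 (3), 10 (2) and 12 (8), and at 4 h vehicle 4 h replicate 17 (93). From 2 h to 4 h every array did but vehicle 4 h replicate 5 (6) and IL-1b 4 h replicate 15 (11), with 2 to 5 calls except without IL-1b 2 h replicate 2 (27). From 2 h to 8 h these were IL-1b 2 h replicate 10 (61), vehicle 8 h replicate 21 (60) and IL-1b 8 h replicates 22 (44) and 26 (59). For vehicle at 4 h they were vehicle 2 h replicates 1 (7), 7 (8) and 9 (8) and vehicle 4 h replicates 1 (5), 3 (7), 5 (11), 7 (9) and 17 (8). For vehicle at 8 h they were vehicle 2 h replicates 1 (88) and 9 (98) and vehicle 8 h replicates 17 (94) and 21 (79).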

Other observations

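The tests of gene lists over time in vehicle mice, their regroupings and the test of the hypothesis below were chosen after results had been seen.

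Over the hours after a vehicle injection, clock genes moved in both directions. Of 15 measured clock genes 7 rose and 3 fell at 8 h against 2 h and 5 did not pass, with 7 higher and 5 lower adjusted over the list alone, and camera called the list (adjusted p = 0.0074, and adjusted p = 0.0733 with an estimated correlation). The fallers were Arntl (-1.42), Npas2 (-1.07) and Nfil3 (-1.53), Npas2 being named after its value was seen. Fatty acid use and fasting genes rose in 4 of 20 at 8 h (Acot2, Cpt1a, Pdk4 and Ucp3), 5 adjusted over the list alone, and the list was called at 8 h (adjusted p = 1.51e-07, and adjusted p = 0.0935 with an estimated correlation) and at 4 h (adjusted p = 5.63e-10, and adjusted p = 0.0733 with an estimated correlation). Of 24 immediate early genes, Nr4a2, Klf4 and Fosl2 fell at 4 h, 0 rose and 21 did not pass, the count of 3 being the same adjusted over the list alone, and camera called the list lower (adjusted p = 0.00124, and adjusted p = 0.54 with an estimated correlation). Glucocorticoid-induced genes were called lower at 8 h with 1 of 26 higher (Pdk4) and 1 lower (Cdkn1a), 1 and 2 adjusted over the list alone (adjusted p = 0.000216, and adjusted p = 0.453 with an estimated correlation). Extracellular matrix and fibroblast markers were called lower at 4 h (median -0.359, adjusted p = 2.03e-07, and adjusted p = 0.467 with an estimated correlation) with 0 of 25 past the threshold by limma and 1 higher adjusted over the list alone, and autophagy genes were called higher then (0 of 24 either way, adjusted p = 0.00108, and adjusted p = 0.364 with an estimated correlation). Other lists were called lower at 8 h, their members being named after their values were seen. They were heat shock genes (0 of 16 past the threshold by limma or over the list alone, adjusted p = 4.67e-05, and adjusted p = 0.15 with an estimated correlation), STAT3 and acute phase genes (Pim1 of 18, 1 over the list alone, adjusted p = 0.000942, and adjusted p = 0.169 with an estimated correlation) and immediate early genes (Nr4a2 and Klf4 of 24, 5 over the list alone, adjusted p = 0.00109, and adjusted p = 0.54 with an estimated correlation). So were ER stress genes (Creld2 of 22, 4 lower and 1 higher over the list alone, adjusted p = 0.00194, and adjusted p = 0.15 with an estimated correlation) and IGF, insulin and myostatin signalling genes (Irs1, Igfbp3 and Smad3 of 25, 3 lower and 1 higher over the list alone, adjusted p = 0.0077, and adjusted p = 0.0837 with an estimated correlation). Both times share the vehicle 2 h arrays.

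A hypothesis from these values was that IL-1b keeps at 8 h what falls in vehicle. Genes that fell from 2 h to 8 h were chosen with 3 of the vehicle 8 h arrays, and IL-1b was compared with those not used, in 10 splits. The median IL-1b effect over the chosen genes had a median of -0.05 over the splits and ran from -0.15 to 0.11, so it went both ways. The hypothesis found no support over the chosen genes as a set, and the held-out arrays are too few to exclude it. Single genes such as Ppp1r3c were not tested for it.

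List calls differed in how often regrouped arrays gave a p as small. For glucocorticoid-induced genes this was 1 of 100 groupings, the real one, at each time, and it was 1 of 100 for amino acid and polyamine genes and for STAT3 and acute phase genes at 4 h and at 8 h. It was also 1 of 100 for ER stress and ATF4 genes at 2 h and 4 h and for matrix markers at 2 h. Immediate early genes and the NF-kB list at 4 h gave 1 of 100 as well. For ubiquitin ligase and FoxO atrophy genes it was 3 of 100 at 4 h and 7 of 100 at 8 h. It was 5 of 100 for the NF-kB list and 8 of 100 for neutrophil markers at 2 h. It reached 39 of 100 for proteasome subunits and for adipocyte markers at 8 h, 33 of 100 for autophagy genes at 8 h and 23 of 100 for endothelial markers at 4 h. These regroupings were drawn at random with repeats possible, and at 8 h only 56 groupings exist, so 1 of 100 overstates the resolution there. All times were regrouped at once, so effects at the other times widened the spread in the regroupings. A small share can therefore come too easily.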
